A study of Homo sapiens with 13 samples.

How the data were processed

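Per the labels' protocols, LNCaP-abl prostate cancer cells were grown in medium with charcoal-stripped serum, transfected with control or target siRNA pools, and harvested 72 h later. RNA was purified on columns, libraries were made with Illumina's TruSeq RNA kit and sequenced on an Illumina HiSeq instrument. Reads were aligned with TopHat and expression was estimated with Cufflinks on the hg19 build, per the submitters' processing notes, which name no versions. How RNA was selected before library preparation is not given in the sources used here. Whether Cufflinks used strand is not given in the sources used here.

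The authors deposited, for each of the 13 libraries, log2 values of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for 22613 gene entries. The lowest deposited value was the log2 of 0.1, so the values were read as log2(FPKM + 0.1). This offset of 0.1 is read from the floor of the values and is stated in no label. The sorted values of the 13 libraries were nearly identical, with a largest spread of 0.0562 on the log2 scale, so the deposited values had already been brought to a common distribution. No label records that step. No counts were used here, so the depth of each library is unknown, and no counting intervals or detection floors are given. An entry at the floor is described as listed at 0, because a failed estimate cannot be told from an absent transcript. Between 1520 and 1821 entries per library were at the floor.

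The values were turned back to FPKM by subtracting the offset of 0.1, set to 0 below 1e-09, and then expressed as log2(FPKM + 1). The offset differed from the one assumed before the data were examined, and the conversion had been fixed in advance for that case. A difference on this scale understates the change of genes with low FPKM. Genes with a mean FPKM of at least 0.5 over the 13 libraries were kept, and 759 entries with symbols of microRNAs or of small nuclear, nucleolar, Cajal body, Y or 5S RNAs were left out because such RNAs are shorter than a sequenced fragment. Other short RNAs, such as vault RNAs, stayed in. This left 15780 genes, of which 535 had only an assembly identifier and 1933 an Ensembl identifier. Of these 1933, 1013 had a symbol in the name table used, and such symbols are given here. PCAT1 was not analysed here as a gene. The reference annotation at hand was of another build than hg19 and was used for names only, so no coordinates are given.

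Each group had 1 library, so no gene was tested between conditions and no p-value across genes is given. Genes at least 2-fold from the control (a difference of 1 on the log2 scale) were counted as a description of these libraries. A gene was called set apart where a library lay at least 1 log2 unit beyond all other 12 libraries. For 25 gene lists fixed beforehand, the median difference from the control was set against 10000 random lists of the same size matched on mean expression in 20 bins, and lists below the 1st or above the 99th percentile are described. Of the 25, 22 had at least 5 measured members. In 2 tests, libraries were compared by permuting their labels 100000 times, each one-sided: whether libraries were low in their own target, and whether 3 pairs of knockdowns chosen beforehand were more alike than other pairs, by Pearson's r across genes after centring each gene on its mean over the 12 knockdowns.

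The genes named were fixed beforehand. They are, for each knockdown, its target, the 6 largest increases and the 6 largest decreases that also differed from the median of the other 11 knockdowns by at least 1 log2 unit in the same direction, and 4 members of each described list. The text gives the 4 members for only 2 lists per library, the described list with the lowest median and the one with the highest median above 0. That restriction was set after the values were seen, and 341 further distinct list members are summarised as counts. The siRNA targets and KLK3 are given wherever they lay at least 1 log2 unit from the control. Some genes that these rules name are not reported here. Values for other genes are marked as chosen after their values were seen. Of the largest changes, the entries without a usable symbol, antisense and read-through entries, and entries listed near 0 in several libraries are mentioned only where stated, since such values may come from reads shared between overlapping genes or near-identical copies.

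The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, small RNA entries kept, differences centred on their median, the median of the other 11 knockdowns in place of the control, Spearman's rho, differences from the control for the similarity of profiles, separate groups of 5 of the other knockdown libraries for each member of a pair (20 splits), and leaving out libraries or pairs in turn. Leaving out 11 entries that switched between under 0.01 FPKM in 3 or more libraries and over 2 FPKM in 3 or more was added after seeing the data. The calculations were tested on simulated data with noise taken from the closest pair of libraries. With 1 changed library against 1 control over 15780 genes, the 2-fold threshold recovered 34% of genes changed 2-fold, 98% of those changed 3-fold and 100% of those changed 4-fold, while 2 unchanged genes passed it. The changed genes were simulated among well expressed ones, and the noise was a normal spread that leaves out extreme genes. The real pair it came from had 145 genes 2-fold apart, so the 2 are no estimate of false calls in these libraries. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.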

Results

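Gene expression was profiled by RNA sequencing in LNCaP-abl cells, an androgen-independent derivative of the LNCaP prostate cancer line, after siRNA knockdown of 12 factors. The 13 libraries comprised 1 control siRNA library and 1 library each for BRCA1, BRCA2, CTCF, EED, EZH2, FOXA1, FOXM1, KDM1A, MALAT1, PCAT1, RAD21 and SMARCA4. There were no replicates, so differences carry no replicate error and are descriptions of these libraries. Read depth is unknown. Values are FPKM, and differences are on the log2(FPKM + 1) scale. The labels state the purpose only as profiling after knockdown, for the modelling of gene regulation in cis.

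The first question was whether each library was low in the gene it was labelled for. FOXM1, a proliferation-associated transcription factor, was at 0.474 FPKM in its own library and 20.1 in the control, a difference of -3.84. RAD21, a cohesin subunit, was at 6.97 against 88.5 FPKM (-3.49). EZH2, the catalytic subunit of the Polycomb repressive complex PRC2, differed by -2.44, the chromatin remodelling ATPase SMARCA4 by -2.40, the insulator protein CTCF by -2.30 and the histone demethylase KDM1A by -2.16. The pioneer factor FOXA1 was at 60.6 against 137 FPKM (-1.16), and EED, another PRC2 subunit, at 4.13 against 8.94 (-0.95). Each of these 8 genes was lower in its own library than in the other 12. Over the 11 targets analysed, the mean difference between the own library and the other knockdowns was -1.39 ± 1.03 (SD, n = 11; one-sided permutation test, p = 1e-05, the smallest the permutations can give).

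The remaining targets did not single out their library. BRCA1, a DNA repair gene, was at 1.83 FPKM in its own library and 11.1 in the control (-2.10), but it was lower still in the siFOXA1 (-2.39) and siFOXM1 (-2.36) libraries. BRCA2 was at 1.23 FPKM in the siBRCA2 library and 3.25 in the control (-0.93), which was the 9th lowest of 13, and it lay 0.27 above the median of the other 11 knockdowns. The long noncoding RNA MALAT1 was at 21.7 FPKM in the library labelled siMALAT1 and 16.4 in the control (0.38), the 12th lowest of 13. Its level therefore goes against that label, and no direction for loss of MALAT1 is drawn from this library. PCAT1 was not analysed here, so the siPCAT1 label has no check.

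**Figure D1:**
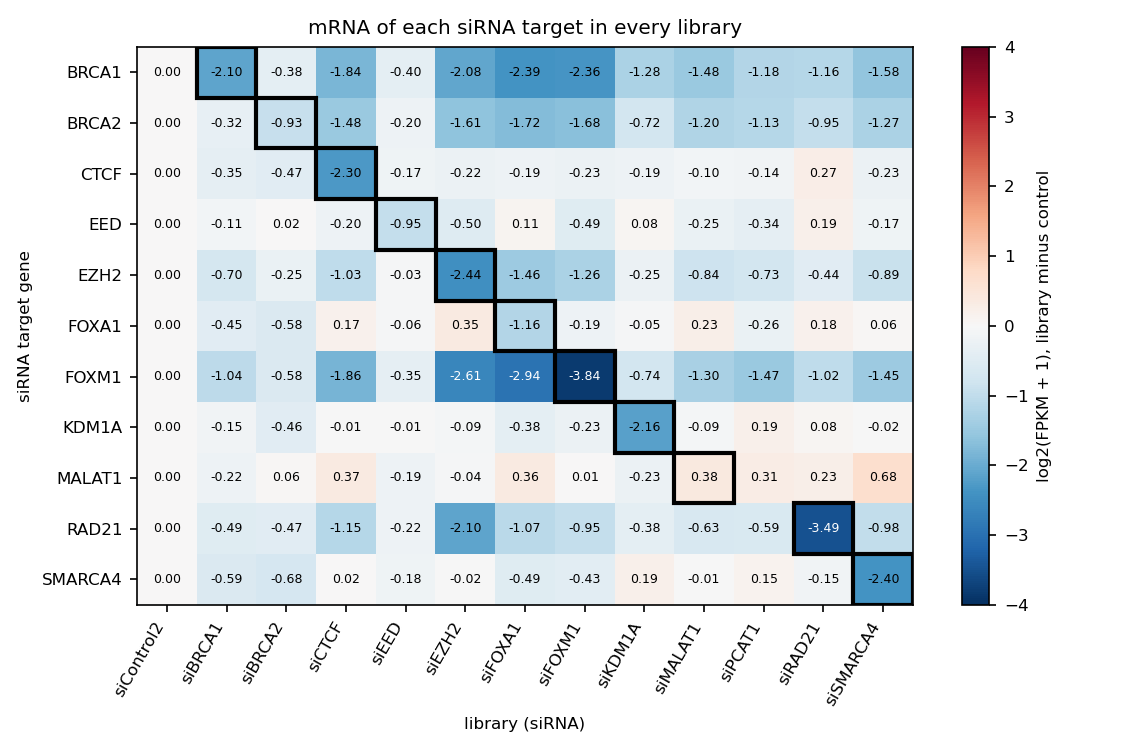
Difference from the control library in log2(FPKM + 1) for 11 siRNA targets (vertical axis) in each of 13 libraries (horizontal axis), with the library of each target outlined. The outlined values run from -3.84 for FOXM1 to 0.38 for MALAT1.

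List medians of cell division genes were below the control in all 12 knockdown libraries, though not every member was. The median of 25 G2/M genes ranged from -3.20 in siFOXA1 to -0.27 in siEED, that of 24 G1/S genes from -2.21 to -0.29, and that of 18 homologous recombination genes from -1.48 to -0.26. In siBRCA2 and siEED, 0 G2/M and 0 G1/S genes were 2-fold lower, and the cyclin CCNB1 was at 76.2 FPKM in siEED against 73.3 in the control. Interferon-stimulated genes had medians of 24 genes from 0.12 in siEED to 3.89 in siFOXM1, past the 99th percentile of matched random lists in 11 libraries, siEED being the exception. The medians of 23 p53 target genes ran from 0.11 in the library labelled siMALAT1 to 1.18 in siCTCF and were past it in 8, not in siEED, siFOXM1, siPCAT1 or the library labelled siMALAT1. Genes of the immediate early response had medians from 0.00 to 0.88 and were past it in 10, not in siBRCA1 or siPCAT1. Of 264 list medians, 113 lay past the 1st or 99th percentile of matched random lists, 66 below and 47 above. By chance 5.28 would, if the members of a list varied as independently as randomly drawn genes. Lists whose members move together break that condition, so the excess is no measure of knockdown effects. All 12 comparisons share the 1 control library. Against the median of the other 11 knockdowns instead, 75 medians lay past these percentiles, and the G2/M, G1/S and homologous recombination medians were above 0 in siBRCA1, siBRCA2, siEED, siKDM1A, siPCAT1 and siRAD21.

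At least 2-fold lower than the control in 6 or more knockdowns were 240 genes, and 44 of them were on the G2/M or G1/S lists. The mitotic kinase PLK1, the anaphase activator CDC20, the ribonucleotide reductase subunit RRM2 and the replication licensing factor MCM5 were among the 26 genes that were 2-fold lower in 10 or more. H2AFX, which encodes the histone variant H2AX, was 2-fold lower in 11. At least 2-fold higher in 10 knockdowns were 7 genes, including the cell cycle inhibitor CDKN1A, the stress-responsive factor ATF3 and the interferon-stimulated gene IFI6. These names were chosen after their values were seen. Simulated unchanged libraries against 1 shared control gave 0 genes lower in 6 or more, and independent lists of the observed sizes would give 0.000642. The simulation holds no real effects and its noise leaves out extreme genes, and the independent lists hold no shared control, so how much of the excess comes from the control library cannot be told here.

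**Figure D2:**
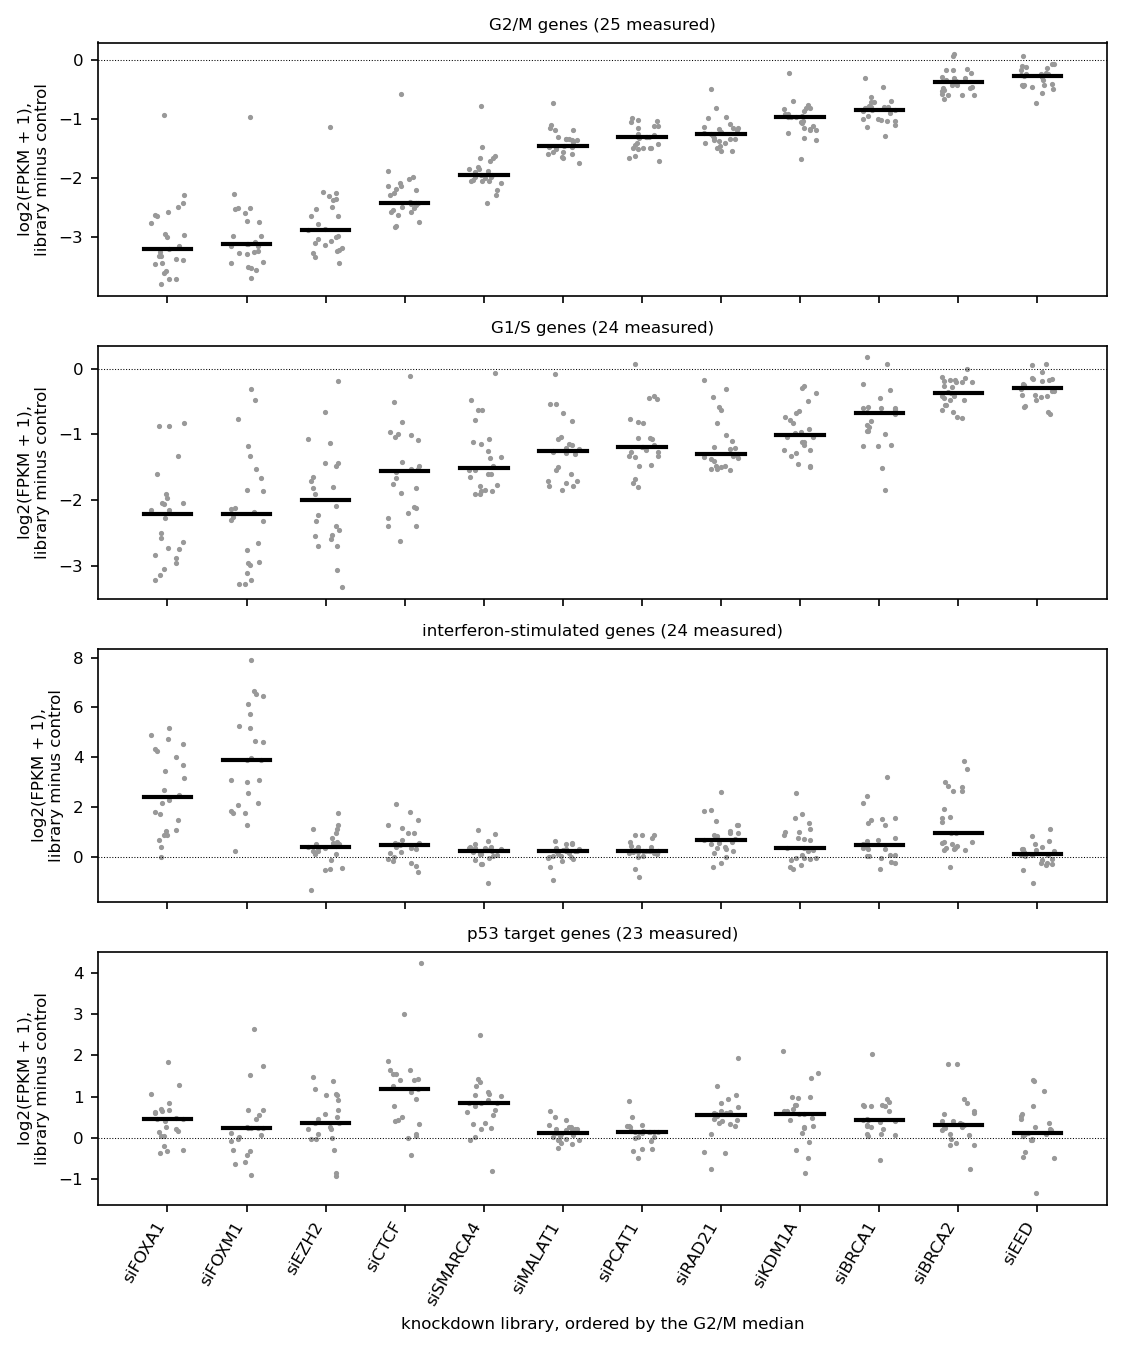
Difference from the control in log2(FPKM + 1) for the members of 4 gene lists (grey points) in each of 12 knockdown libraries, with the list median as a black bar. Libraries are ordered by the G2/M median, from -3.20 in siFOXA1 to -0.27 in siEED, and the highest interferon median is 3.89 in siFOXM1.

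The control library was not an outlier by size. No gene lay at least 1 log2 unit beyond all knockdowns in it, against 116 genes in siFOXA1, 80 in siFOXM1, 30 in siEZH2, 28 in siCTCF, 15 in siRAD21, 7 in siEED, 6 each in siKDM1A and the library labelled siMALAT1, 4 each in siBRCA1, siBRCA2 and siSMARCA4, and 1 in siPCAT1. The genes highest in the control relative to the nearest knockdown were H2AFX (0.94), the apoptosis inhibitor BCL2 (0.67), the histone gene HIST1H2AB (0.66), C4orf46 (0.64), the cell cycle repressor E2F8 (0.62) and SCARA3 (0.60). The lowest included the interferon-stimulated gene OASL and RARRES3, by 0.62 and 0.56. With a pseudocount of 0.1 the control had 13 genes set apart. Of the 30 genes in siEZH2, 14 were of the GAGE family of near-identical copies, and 16 remain without them.

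**Figure D3:**
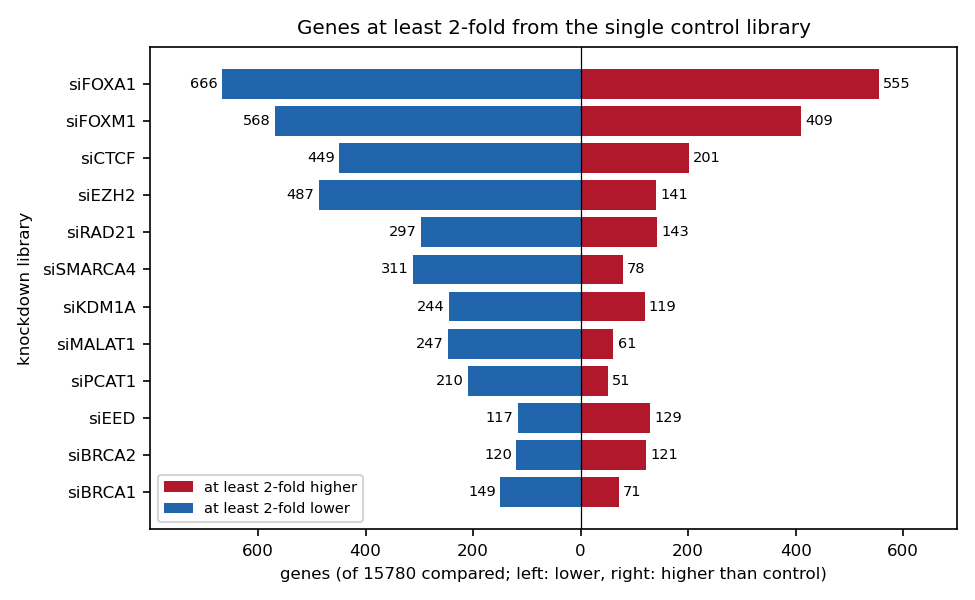
Number of genes at least 2-fold lower (left) or higher (right) than the single control library in each of 12 knockdown libraries, of 15780 genes. The largest sum is 1221 in siFOXA1 and the smallest 220 in siBRCA1.

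The numbers of genes at least 2-fold from the control follow for each knockdown. They depend on the pseudocount: at 0.1 they were 1.5 times larger or more in every library, from 624 in siPCAT1 to 2142 in siFOXA1. They also depend on the reference: against the median of the other 11 knockdowns, they were more than 1.5 times smaller in 10 libraries, siBRCA2 and siEED being the exceptions.

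In the siFOXM1 library, interferon-stimulated genes stood far above the control. OASL was at 437 FPKM against 0.831 (7.90), IFIT2 at 327 against 2.22 (6.67), IFI6 at 622 against 5.65 (6.55) and IFIT1 at 269 against 2.10 (6.44). Of 24 list members, 23 were at least 2-fold higher. RARRES3 was higher by 6.14 and TM4SF18-AS1, listed by its Ensembl identifier, by 6.15. The G2/M median was -3.13, with 24 of 25 members 2-fold lower, among them the ubiquitin-conjugating enzyme UBE2C (-3.69), CDC20 (-3.56), the kinetochore protein CENPF (-3.52) and the mitotic kinesin KIF2C (-3.51). The mitotic protein TROAP (-3.77), thymidine kinase TK1 (-3.57) and CEP55 (-3.52) were also among the largest decreases. The medians were -2.21 for G1/S genes, -1.48 for homologous recombination genes, -0.41 for cohesin and CTCF, 0.46 for stress response genes, 0.88 for immediate early genes and 0.78 for 7 EZH2-silenced genes. BRCA1 (-2.36), BRCA2 (-1.68) and EZH2 (-1.26) were lower than in the control. In total, 409 genes were higher and 568 lower.

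The siFOXA1 library had the largest number of genes 2-fold from the control, 555 higher and 666 lower. Interferon-stimulated genes were high here as well, with a median of 2.38 and 19 of 24 members at least 2-fold higher. OASL was higher by 5.19, IFI6 by 4.90, IFIT1 by 4.74 and IFIT2 by 4.54, and RARRES3 by 4.45. The chemokine CXCL10 was at 21.2 FPKM and was listed at 0 in the control. The G2/M median was -3.20, with topoisomerase TOP2A (-3.80), CDC20 (-3.71), HMMR (-3.71) and CENPF (-3.61) lowest, and the largest decreases also included the transcription factor MYBL2 (-3.68) and the spindle protein TACC3 (-3.61). The G1/S median was -2.21, that of homologous recombination genes -1.35, of cohesin and CTCF -0.56 and of cholesterol and fatty acid synthesis genes -0.32, while those of p53 target and immediate early genes were 0.45 and 0.75. FOXM1 (-2.94), BRCA1 (-2.39), BRCA2 (-1.72), EZH2 (-1.46) and RAD21 (-1.07) were lower than in the control.

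In the siCTCF library, CDKN1A was at 440 FPKM against 22.5 in the control (4.23). The p53 target list had its highest median here, 1.18, with 13 of 23 members 2-fold higher, among them the growth factor GDF15 (40.1 against 4.13 FPKM), SESN2 (1.87) and SPATA18 (1.65). The clusterin-like gene CLUL1 was higher by 2.53 and the antisense transcript PXN-AS1 by 2.54. The G2/M median was -2.43, with 24 of 25 members 2-fold lower, including CDC20 (-2.83), the survivin gene BIRC5 (-2.81), PLK1 (-2.75) and TOP2A (-2.63). NUSAP1 (-2.89), CDCA3 (-2.84), ANLN (-2.78) and NUF2 (-2.78), all with roles in mitosis, were among the largest decreases. The medians were -1.55 for G1/S, -1.44 for homologous recombination and -0.48 for cohesin and CTCF, the siRNA target included. They were 0.50, 0.55 and 0.46 for stress response, immediate early and interferon-stimulated genes. The last pair turned to -0.032 and -0.10 against the other knockdowns. FOXM1 (-1.86), BRCA1 (-1.84), BRCA2 (-1.48), RAD21 (-1.15) and EZH2 (-1.03) were lower than in the control. In total, 201 genes were higher and 449 lower.

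In the siEZH2 library, all 25 G2/M genes were at least 2-fold lower, with a median of -2.87. CDC20 (-3.45), PLK1 (-3.35), HMMR (-3.27) and TOP2A (-3.24) were lowest on the list, and NUSAP1 (-3.50), ANLN (-3.43), DLGAP5 (-3.42) and the replication factor CDC45 (0.485 against 13.8 FPKM) were among the largest decreases. The collagen gene COL5A2 was higher by 1.89 and the matrix protein gene SPON2 by 1.76. Immediate early genes had a median of 0.80, with ATF3 higher by 1.99, DUSP1 by 1.25, JUN by 1.04 and EGR1 by 0.92, although ATF3 was -0.012 from the other knockdowns. The medians were -2.00 for G1/S, -1.30 for homologous recombination and -0.37 for PRC2 members, the target EZH2 included. They were -0.37 for cohesin and CTCF and -0.36 for hypoxia and glycolysis genes. Those of luminal markers, stress response, p53 target and interferon-stimulated genes were 0.29, 0.34, 0.37 and 0.38, the last turning to -0.25 against the other knockdowns. FOXM1 (-2.61), RAD21 (-2.10), BRCA1 (-2.08) and BRCA2 (-1.61) were lower than in the control. In total, 141 genes were higher and 487 lower.

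In the siSMARCA4 library, the p53 target list had a median of 0.84, with 8 of 23 members 2-fold higher. CDKN1A was higher by 2.48, PHLDA3 by 1.43, SESN2 by 1.34 and GDF15 by 1.26, the last being -0.14 from the other knockdowns. The secreted trefoil peptide gene TFF1 was higher by 1.67. G2/M genes had a median of -1.95, with HMMR (-2.43), TTK (-2.30), PLK1 (-2.21) and CDC20 (-2.08) lowest. The ribosomal protein gene RPL10, which has near-identical copies in the genome, was at 41.0 FPKM against 203 (-2.28). The medians were -1.51 for G1/S, -1.06 for homologous recombination, -0.33 for cohesin and CTCF, -0.28 for PRC2, -0.25 for hypoxia and glycolysis and -0.19 for cholesterol and fatty acid synthesis genes. They were 0.22 for androgen-induced genes, 0.23 for luminal markers, 0.24 for interferon-stimulated genes, 0.37 for immediate early genes and 0.39 for stress response genes. Against the other knockdowns the interferon median turned to -0.36 and that of PRC2 to 0.018. BRCA1 (-1.58), FOXM1 (-1.45) and BRCA2 (-1.27) were lower than in the control. In total, 78 genes were higher and 311 lower, and only 51 genes lay 2-fold from the median of the other knockdowns.

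In the siRAD21 library, the insulin-like growth factor binding protein gene IGFBP3 was at 9.87 FPKM against 54.5 in the control (-2.35), the RNA-binding protein gene RBM24 differed by -1.86 and BLOC1S5, listed at 0.0123 FPKM, by -2.17. The relaxin gene RLN1 was higher by 2.11 and SLC37A4 by 2.69, and the unnamed assembly entries XLOC_007305 and XLOC_007635 were higher by 3.03 and 2.00. The difference of SLC37A4 rests on values near 0, as it ranged from 0.0273 to 7.70 FPKM over the 13 libraries. The antisense transcript HOXA11-AS differed by -1.88. Interferon-stimulated genes had a median of 0.68, with IFI6 higher by 2.58, IFIT1 by 1.89, OASL by 1.83 and ISG15 by 1.41. G1/S genes had the lowest median, -1.30, with MCM4 (-1.54), GINS2 (-1.52), MCM10 (-1.52) and the cyclin CCNE2 (-1.49) lowest. Of these, only CCNE2 was also below the median of the other knockdowns. The medians were -1.26 for G2/M, -0.89 for homologous recombination, 0.30 for immediate early genes, turning to -0.19 against the other knockdowns, 0.41 for stress response and 0.56 for p53 target genes. BRCA1 (-1.16) and FOXM1 (-1.02) were lower than in the control but above the median of the other knockdowns. In total, 143 genes were higher and 297 lower.

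In the siKDM1A library, the protease inhibitor gene SLPI was higher by 2.23 and the kallikrein gene KLK4 by 1.98, and the pseudogene ADCY10P1 by 1.84. The actin-binding protein gene CFL2 (-1.80) and the ribonuclease gene RNASE4 (-1.77) were among the largest decreases. The p53 target list had a median of 0.58, with CDKN1A higher by 2.11, GDF15 by 1.57, SESN2 by 1.45 and AEN by 0.99. G1/S genes had a median of -1.003, with CDC6 (-1.49), RRM2 (-1.48), MCM5 (-1.45) and TYMS (-1.33) lowest, all of which lay above the median of the other knockdowns. The medians were -0.97 for G2/M, -0.75 for homologous recombination, -0.51 for 6 neuroendocrine markers, -0.28 for cohesin and CTCF and -0.22 for cholesterol and fatty acid synthesis genes. They were 0.52 for 5 mesenchymal markers, 0.48 for immediate early, 0.34 for interferon-stimulated and 0.21 for stress response genes. The last 2 turned to -0.026 and -0.12 against the other knockdowns, and that of cohesin and CTCF to 0.025. BRCA1 differed by -1.28 but lay above the median of the other knockdowns. In total, 119 genes were higher and 244 lower.

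In the siBRCA1 library, the Notch ligand gene JAG1 was at 15.7 FPKM against 60.1 in the control (-1.87), the acyl-protein thioesterase gene LYPLA1 differed by -1.77 and LOC145837 by -2.00. LOC145837 was listed at 0.0807 FPKM there and between 0.000429 and 4.23 FPKM in the other 11 knockdowns, so its difference rests on values near 0. IFI6 was higher by 3.20, the telomerase RNA TERC by 1.97, the RNase P RNA RPPH1 by 1.88 and LINC00648 by 1.66. With small RNA entries kept, 241 genes were higher and 249 lower in this library, against 71 and 149 without them. Such entries thus moved both ways, and no meaning is drawn from TERC or RPPH1, which are also noncoding RNAs. Interferon-stimulated genes had a median of 0.46, with OASL higher by 2.44, IFIT1 by 2.17 and RSAD2 by 1.55. For G2/M genes the median was -0.85, with KIF20A (-1.28), PLK1 (-1.14), CDC20 (-1.10) and CCNB1 (-1.04) lowest, and these 4 lay above the median of the other knockdowns. The medians were -0.67 for G1/S, -0.53 for homologous recombination, -0.40 for neuroendocrine markers, -0.32 for cohesin and CTCF and -0.25 each for SWI/SNF members, androgen-induced genes and MALAT1 neighbours. They were 0.42 each for stress response and p53 target genes. Against the other knockdowns the stress response median turned to -0.010 and that of cohesin and CTCF to 0.034. FOXM1 differed by -1.04 but lay above the median of the other knockdowns. In total, 71 genes were higher and 149 lower.

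In the siBRCA2 library, interferon-stimulated genes led the increases, with a median of 0.94 and 11 of 24 members 2-fold higher. IFI6 was higher by 3.85, OASL by 3.51, RSAD2 by 2.83 and IFI27 by 2.80, and IFIT1 was at 23.8 against 2.10 FPKM. The neuroserpin gene SERPINI1 was at 23.9 FPKM against 118 in the control (-2.25), below all other libraries. The cancer-testis antigen gene GAGE6, a member of a family of near-identical copies, differed by -2.08. On the G2/M list the median was -0.39, with CENPF (-0.66), CDC25B (-0.60), CCNB1 (-0.60) and CDC20 (-0.59) lowest, and these 4 lay above the median of the other knockdowns. The medians were -0.37 for G1/S, -0.26 for homologous recombination, -0.25 for SWI/SNF, -0.22 for MALAT1 neighbours and -0.21 for cohesin and CTCF. They were 0.19 for androgen-induced, 0.30 for p53 target, 0.38 for immediate early, 0.42 for hypoxia and glycolysis and 0.53 for stress response genes. Against the other knockdowns the p53 target median turned to -0.12 and that of cohesin and CTCF to 0.12. In total, 121 genes were higher and 120 lower.

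In the siEED library, the matricellular protein gene CYR61 was higher by 2.47, the transglutaminase gene TGM3 by 2.17 and the stress-responsive gene CHAC1 by 2.09. The glucagon gene GCG was at 1.66 FPKM against 16.6 in the control (-2.73). Immediate early genes had a median of 0.40, with ATF3 higher by 2.36, DUSP1 by 1.26, FOS by 1.08 and JUN by 0.86. Neuroendocrine markers had a median of -0.37, with NCAM1 (-0.76), STMN2 (-0.74), SYT1 (-0.40) and ENO2 (-0.35) lowest, the last lying 0.17 above the other knockdowns. The cell division medians were the closest to the control of all 12 libraries, -0.27 for G2/M and -0.29 for G1/S. The medians were -0.26 each for homologous recombination and for cholesterol and fatty acid synthesis genes, -0.21 for SWI/SNF members and 0.19 for stress response genes, the last turning to -0.081 against the other knockdowns. In total, 129 genes were higher and 117 lower.

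In the library labelled siMALAT1, the glucocorticoid-induced gene TSC22D3 was at 77.4 FPKM against 25.5 in the control (1.56), TFF1 was higher by 1.43 and the 5-oxoprolinase gene OPLAH by 2.68. The protease inhibitor gene CSTB (-1.70) and the nucleolar protein genes NPM1 (-1.42) and NCL (-1.37) were lower, and UBXN8, listed at 0.000916 FPKM, by -2.68. Among G2/M genes the median was -1.46, with CENPF (-1.74), TOP2A (-1.67), TPX2 (-1.64) and CDC20 (-1.60) lowest. Luminal markers had a median of 0.25, with ELF3 higher by 0.61, KRT8 by 0.46, HOXB13 by 0.40 and CLDN7 by 0.38. The medians were -1.25 for G1/S, -0.91 for homologous recombination, -0.28 for cohesin and CTCF, -0.24 for PRC2, -0.18 for hypoxia and glycolysis and -0.17 for cholesterol and fatty acid synthesis genes, and 0.22 each for interferon-stimulated and stress response genes and 0.24 for immediate early genes. The 3 last medians turned to -0.35, -0.43 and -0.40 against the other knockdowns, and that of cohesin and CTCF to 0.0020. BRCA1 (-1.48), FOXM1 (-1.30) and BRCA2 (-1.20) were lower than in the control, though BRCA1 and FOXM1 lay above the median of the other knockdowns. In total, 61 genes were higher and 247 lower, which became 76 and 61 against the median of the other knockdowns.

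In the siPCAT1 library, the zinc finger gene MYNN was at 35.9 FPKM against 8.70 in the control (1.93), LINC00648 was higher by 2.05 and the glucose-6-phosphate transporter gene SLC37A4 by 3.01. SLC37A4 ranged from 0.0273 to 7.70 FPKM over the 13 libraries, so its difference rests on values near 0. IGFBP3 differed by -1.51, and NRAV, listed by its Ensembl identifier, by -2.90. NRAV was listed at 0.0245 FPKM there and 6.63 in the control, so its difference also rests on a value near 0. The G2/M median was -1.31, with BIRC5 (-1.72), AURKB (-1.67), PLK1 (-1.63) and CENPF (-1.50) lowest, the last lying above the median of the other knockdowns. The interferon list had a median of 0.23, with OASL higher by 0.88, IFIT1 by 0.87, IFI6 by 0.87 and IFIT2 by 0.76, and these 4 lay below the median of the other knockdowns. The medians were -1.19 for G1/S, -0.79 for homologous recombination and -0.21 for cohesin and CTCF. Against the other knockdowns the interferon median turned to -0.33 and that of cohesin and CTCF to 0.085. FOXM1 (-1.47), BRCA1 (-1.18) and BRCA2 (-1.13) were lower than in the control, though BRCA1 and BRCA2 lay above the median of the other knockdowns. In total, 51 genes were higher and 210 lower, and this library and the one labelled siMALAT1 had the fewest genes 2-fold apart of all 78 pairs, 145.

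Some of the largest changes were entries that switched between absence and presence. RPL21, a ribosomal protein gene with many processed copies, ranged from 5.99e-05 to 26.2 FPKM and was under 0.01 in 4 libraries. VTRNA1-2, a vault RNA, ranged from 0 to 72.2 FPKM and was under 0.01 in 4, and SERF1A ranged from 0.000338 to 8.33 FPKM and was under 0.01 in 3. Of the 15780 genes, 11 were under 0.01 FPKM in 3 or more libraries and over 2 in 3 or more, these 3 among them, and they made up between 4 and 10 of the 2-fold genes of a library. Outside that rule, DYNLL1-AS1 was under 0.01 FPKM in 7 libraries and reached 8.53, ZSWIM8-AS1 was under it in 9 and reached 6.40, and PLGLB2 was under it in 2 and reached 6.36. These entries are given no direction.

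Lists not past the percentiles in any library were the CoREST members, with medians from -0.19 to 0.17, the clustered protocadherins, from -0.16 to 0.41, the PCAT1 neighbours and MYC locus, from -0.26 to 0.26, and the ribosomal protein genes, from -0.05 to 0.10. The EZH2-silenced list had a median of -0.06 in siEZH2 and 0.24 in siEED, neither past the percentiles. Only 7 of its 16 genes were measured, and only 5 of the 25 clustered protocadherins. Genes silent in nearly all libraries fail the filter on mean FPKM, so these medians say little about loss of silencing. The neighbours of MALAT1 had a median of 0.08 in the library labelled siMALAT1, and those of PCAT1 -0.06 in the siPCAT1 library. KLK3, which encodes PSA, was between 0.0165 and 0.525 FPKM, too low for a difference of 1 log2 unit to occur on this scale. The androgen-repressed, basal and immune lists had fewer than 5 measured members. Of the androgen-repressed genes, DDC was between 35.1 and 447 FPKM, OPRK1 between 23.6 and 104, CAMK2N1 between 3.46 and 98.4 and UGT2B11 between 0.184 and 9.56. In the siFOXA1 library, DDC differed by -2.87 from the control and CAMK2N1 was higher by 3.71. Of the basal markers, ITGA6 was between 8.25 and 19.3 FPKM, DST between 4.28 and 13.9 and ITGB4 between 1.40 and 4.13. Of the immune markers, PTPRC was between 0.1004 and 3.14 FPKM, CD68 between 4.07 and 11.1 and LYZ between 3.36 and 4.76.

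The last comparison asked whether knockdowns of partner proteins gave similar profiles. The siBRCA1 and siBRCA2 profiles were the most alike of all 66 pairs, with r = 0.35 across genes. Pairs not chosen beforehand came next. They were the library labelled siMALAT1 with siPCAT1 (0.34), siBRCA2 with siEED (0.29), siFOXA1 with siFOXM1 (0.26) and siBRCA1 with siEED (0.24). Both siBRCA1 and siBRCA2 were thus also close to siEED, which was not their chosen partner. In this order, siBRCA1, siBRCA2 and siEED had the fewest genes 2-fold from the control (220, 241 and 246). Their G2/M medians were also the closest to it (-0.85, -0.39 and -0.27). Their likeness therefore cannot be told apart from a small distance to the control. BRCA2 was also only the 9th lowest of 13 in the siBRCA2 library. The siCTCF and siRAD21 profiles had r = -0.15, ranked 46, and the siEZH2 and siEED profiles r = -0.19, ranked 53. The mean of the 3 pairs chosen beforehand was 0.00 against -0.09 over all 66, which did not pass the test (one-sided permutation test, p = 0.187). Without the siBRCA1 and siBRCA2 pair the mean was -0.17, below that of all pairs. Genes are not independent replicates, and centring alone gave -0.09 for simulated unchanged libraries. As differences from the shared control, the mean r of the 3 pairs was 0.47, which did not pass the test either (one-sided permutation test, p = 0.383). Simulated unchanged libraries gave 0.49 over all 66 pairs in that setting. The mean covariance over all 66 pairs was 0.0814 observed and 0.0263 simulated, so the libraries shared more than the simulated noise of the control. That value covers all pairs and says nothing about the 3 chosen ones.

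**Figure D4:**
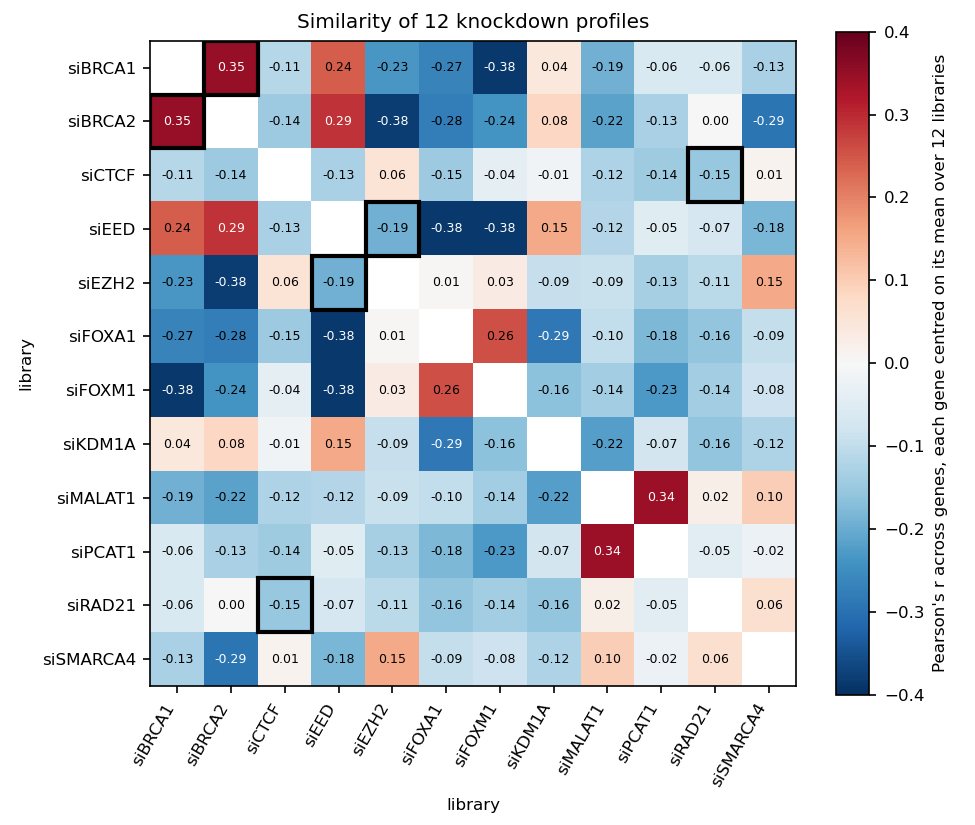
Pearson's r across 15780 genes between the profiles of 12 knockdown libraries (both axes), each gene centred on its mean over these libraries, with the 3 pairs chosen beforehand outlined. The highest value is 0.35 for siBRCA1 and siBRCA2, and the outlined values for siCTCF with siRAD21 and siEZH2 with siEED are -0.15 and -0.19.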

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

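Leaving out the switching entries was chosen after the data were seen, and it left all 12 counts of 2-fold genes within 1.5 times. Quantile normalization moved no value, since the deposited values already shared 1 distribution, so it tests nothing. No paired analysis was possible because each group had 1 library. Depth is unknown, so its limits were not assessed. The target test kept its direction and its side of the threshold under all alternatives, and so did the similarity test, except that without the siBRCA1 and siBRCA2 pair the mean r was -0.17 (one-sided permutation test, p = 0.771), the range over pairs left out in turn being -0.17 to 0.098. The r of siCTCF and siRAD21 was 0.50 as differences from the control, a setting in which all pairs share the control. The cause of the changes below was not tested, except that smaller pseudocounts enlarge differences of genes with low FPKM and kept small RNA entries add genes.

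With a pseudocount of 0.1, the genes at least 2-fold from the control numbered 708 in siBRCA1, 724 in siBRCA2, 1256 in siCTCF, 736 in siEED, 1219 in siEZH2, 2142 in siFOXA1, 1687 in siFOXM1, 982 in siKDM1A, 706 in the library labelled siMALAT1, 624 in siPCAT1, 1032 in siRAD21 and 798 in siSMARCA4. With small RNA entries kept, they numbered 490 in siBRCA1, 460 in siBRCA2, 520 in siEED, 607 in siKDM1A, 554 in the library labelled siMALAT1, 487 in siPCAT1, 696 in siRAD21 and 647 in siSMARCA4. Against the median of the other 11 knockdowns, they numbered 127 in siBRCA1, 220 in siCTCF, 264 in siEZH2, 772 in siFOXA1, 507 in siFOXM1, 136 in siKDM1A, 137 in the library labelled siMALAT1, 121 in siPCAT1, 177 in siRAD21 and 51 in siSMARCA4. Other counts of 2-fold genes stayed within 1.5 times, though the balance of higher and lower genes moved by more than 10 points in several. With this reference it was 163 higher and 78 lower in siBRCA2, 160 and 75 in siEED, 76 and 61 in the library labelled siMALAT1, 47 and 74 in siPCAT1 and 19 and 32 in siSMARCA4. With a pseudocount of 0.1 it was 429 and 790 in siEZH2, 247 and 459 in the library labelled siMALAT1, 202 and 422 in siPCAT1 and 278 and 520 in siSMARCA4. With small RNA entries kept it was 241 and 249 in siBRCA1, 176 and 378 in the library labelled siMALAT1, 163 and 324 in siPCAT1 and 206 and 441 in siSMARCA4.

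Genes set apart in 1 library numbered, with a pseudocount of 0.1, 17 in siBRCA1, 30 in siBRCA2, 60 in siCTCF, 13 in the control, 29 in siEED, 242 in siFOXA1, 21 in siKDM1A, 26 in the library labelled siMALAT1, 21 in siPCAT1, 43 in siRAD21 and 10 in siSMARCA4. With no filter on low values, they numbered 8 in siBRCA2, 1 in the control, 10 in the library labelled siMALAT1 and 2 in siPCAT1.

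Against the median of the other 11 knockdowns, 75 list medians instead of 113 lay past the percentiles, and 38 of the 113 changed sign. In siBRCA1, siBRCA2, siEED, siKDM1A, siPCAT1 and siRAD21, in this order, the G1/S medians were 0.59, 0.90, 1.08, 0.33, 0.14 and 0.064, the G2/M medians 0.67, 1.08, 1.18, 0.42, 0.11 and 0.15, and the homologous recombination medians 0.51, 0.80, 0.71, 0.29, 0.14 and 0.11. Those of cohesin and CTCF were 0.034 in siBRCA1, 0.12 in siBRCA2, 0.025 in siKDM1A, 0.0020 in the library labelled siMALAT1 and 0.085 in siPCAT1, and that of PRC2 members was 0.018 in siSMARCA4. Immediate early medians were -0.032 in siCTCF, -0.40 in the library labelled siMALAT1 and -0.19 in siRAD21. Interferon medians were -0.10 in siCTCF, -0.25 in siEZH2, -0.026 in siKDM1A, -0.35 in the library labelled siMALAT1, -0.33 in siPCAT1 and -0.36 in siSMARCA4. The p53 target median was -0.12 in siBRCA2, and stress response medians were -0.010 in siBRCA1, -0.081 in siEED, -0.12 in siKDM1A and -0.43 in the library labelled siMALAT1.

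With the same reference, 32 of 251 named differences changed sign. In siBRCA1 they were KIF20A 0.14, PLK1 0.49, CDC20 0.50, CCNB1 0.27 and FOXM1 0.42. In siBRCA2 they were BRCA2 0.27, CENPF 1.08, CDC25B 0.21, CCNB1 0.72 and CDC20 1.01. ENO2 was 0.17 in siEED, ATF3 -0.012 in siEZH2 and GDF15 -0.14 in siSMARCA4. In siKDM1A they were CDC6 0.039, RRM2 0.25, MCM5 0.063, TYMS 0.068 and BRCA1 0.30, and in the library labelled siMALAT1 BRCA1 0.092 and FOXM1 0.15. In siPCAT1 they were CENPF 0.24, OASL -0.93, IFIT1 -0.68, IFI6 -1.69, IFIT2 -0.52, BRCA1 0.40 and BRCA2 0.074. In siRAD21 they were MCM4 0.068, GINS2 0.27, MCM10 0.25, BRCA1 0.42 and FOXM1 0.43. Of the 341 list members not named, 103 changed sign, 152 kept it and moved, and 86 stayed within their spread, while a pseudocount of 0.1 moved 25. That pseudocount moved 79 of the 251 named differences, and it changed the sign of none of either kind.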

Other observations

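All tests and list relations in this part were chosen after the results were seen, and so was the bound of -1.9 used for G2/M medians, which was set with the values in view. The genes of the next paragraph were also chosen after their values were seen.

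In the siFOXA1 library, SPDEF (-2.25) and SLC45A3 (-1.55) lay below all other libraries by at least 1 log2 unit, while the phospholipase gene PLA2G2A (4.17) lay above them. Both of the former are on the androgen-induced list, whose median there was -0.16 and not past the percentiles, with 7 of 19 members 2-fold lower and 2 higher, and the luminal median was 0.29, not past them either. In the siFOXM1 library, the interferon gene IFNL1 (4.04), the chemokine gene CCL5 (2.53) and the antigen presentation gene B2M (1.79) lay above all others. B2M differed by -1.76 in the siCTCF library, below all others.

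The median of G2/M genes was lower than in the control in every knockdown library, though in siBRCA2 and siEED 0 of 25 members were 2-fold lower. A control that alone stands high is argued against as the whole cause, since the 12 medians spanned 2.93 log2 units, and a high control would lower all 12 by about the same amount. An interferon response as the whole cause was asked of 5 libraries with a G2/M median of -1 or lower and an interferon median under 0.5. All 5 interferon medians were still past the 99th percentile of matched random lists, so they cannot exclude this cause. The sizes of the 2 medians did not always go together. In siBRCA2 the interferon median was 0.94 and the G2/M median -0.39, while in siEZH2 they were 0.38 and -2.87. Induction of p53 target genes as the whole cause is argued against, though weakly, by 3 libraries with such a G2/M median and a p53 target median under 0.25. These were siFOXM1 (0.23), siPCAT1 (0.15) and the library labelled siMALAT1 (0.11). None of these medians was past the 99th percentile, though all were above 0. An interferon response, a part played by the control library and slower division after loss of the target stay open, the last untested. MALAT1 was, however, higher by 0.38 in the library labelled siMALAT1, whose G2/M median was -1.46.

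Interferon-stimulated genes were far higher in the siFOXM1 and siFOXA1 libraries than in the others. The 3 other libraries with a G2/M median under -1.9, siEZH2 (-2.87), siCTCF (-2.43) and siSMARCA4 (-1.95), had interferon medians between 0.24 and 0.46. Low expression of G2/M genes as a sufficient cause is thus argued against only at the depth these 3 reached. Whether the deeper loss in siFOXM1 (-3.13) and siFOXA1 (-3.20) is enough cannot be told. Only siEZH2 came near it, and that library alone, with an interferon median of 0.38, would exclude nothing. Loss of FOXM1 mRNA cannot be told apart, because siEZH2, the only near case, had FOXM1 higher by 0.34 than siFOXA1. For immune cells in the culture, the labels give no source, since they name LNCaP-abl cells alone. PTPRC was at 1.10 FPKM in siFOXM1 but at 0.1004 in siFOXA1, the lowest of 13 libraries. It was highest in siRAD21 (3.14), whose interferon median was 0.68. CD68 was higher by 0.96 in siFOXM1 and 0.71 in siFOXA1 but also by 0.78 in siCTCF (interferon median 0.46). LYZ was higher by 0.16 in siFOXM1 and 0.19 in siFOXA1 but by 0.37 in siBRCA2. PTPRC thus did not follow the interferon medians, but its values are low, so these markers alone exclude nothing. A response to the siRNA pools themselves stays open and was not tested.

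MALAT1 was not lower in the library labelled siMALAT1. The lowest of the other 12 lay only -0.27 from their median, which argues against a swap with another library analysed here only if the siRNA lowered MALAT1. After a failed knockdown no library would be low, whatever the labels. A library equal to an untargeted transfection cannot be told apart, as its pair with the control ranked 15 of 78 by fewest genes apart and a repeat of the control is not at hand to set that against. A failed knockdown, with or without a swap of labels, and a swap with a library not analysed here stay open.

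Across the 12 knockdowns, interferon and G2/M medians had r = -0.60 (permutation p = 0.0253, adjusted over 3 relations 0.0758) and Spearman's rho = -0.42 (adjusted p = 0.433). Without siFOXA1 and siFOXM1, r was 0.17. For p53 target and G2/M medians r was -0.27 (permutation p = 0.395) and rho -0.22, with r = -0.12 without siCTCF and siSMARCA4. For p53 target and interferon medians r was -0.15 (permutation p = 0.634, n = 12 libraries) but rho 0.34 (permutation p = 0.289), with r = 0.039 without those libraries.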
